A study of Mus musculus with 36 samples.

How the data were processed

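Gene expression was measured with 1-colour Affymetrix arrays on total RNA from mouse diaphragm, the main breathing muscle, taken from control mice and from mdx mice, which carry a mutation of the dystrophin gene Dmd. Per the labels, animals of 7, 14, 23, 28, 56 and 112 days were used, with 3 arrays for each age and genotype, which gave 12 groups and 36 arrays. The labels name the standard protocol of the array maker and give no strain, pooling or date, and the software that turned scans into values is not given in the sources used here. The replicates of a group are numbered, but nothing says that they came from separate animals, so p-values measure only the spread between these arrays, which may be technical.

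The deposited values are the intensity of each probe set on a linear scale, 1 column per array. The mean of the values between percentiles 2 and 98 lay between 1499.2 and 1499.7 on all 36 columns, so the columns had already been brought to a common level, and they were used as deposited. The lowest value in the table was 0.3 and the highest 92204. The median signal of an array ran from 450.6 to 723.4, and no detection calls were used. For arrays, precision is limited by the number of arrays per group. All 36 columns were matched to a sample by their labels.

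The table holds 12488 probe sets, of which 66 are the array maker's controls and were left out of the tests. In the platform annotation, 10833 of the others had 1 gene symbol, 396 had several and 1193 had none; 10817 were matched to a mouse reference gene and 0 symbols were updated. Probe sets with several symbols or none were tested and counted but not named.

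Values were analysed as log2(value + 32), so a log2 difference understates the change of a dim gene. Probe sets were kept where at least 3 arrays lay above percentile 40 of all values, a signal of 374.5, which left 9291 probe sets, covering 6794 genes with 1 symbol. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 12 groups over all 36 arrays, with moderated variances that follow a trend on mean signal (eBayes), 24 residual degrees of freedom and a median of 6.14 prior degrees of freedom. Unless another test is named, p-values are from limma with Benjamini-Hochberg adjustment within a comparison, and an adjusted p under 0.05 is called a rise or a fall. The comparisons were mdx minus control at each age, its mean over the 6 ages, an F test of whether it depended on age, its difference between 14 and 23 days and between 28 and 112 days, and control at 112 days minus control at 7 days.

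Before the data were examined, 33 gene lists naming 668 genes were fixed, covering muscle, immune, matrix, metabolic and stress genes and markers of other cell types that a piece of diaphragm may hold. For each gene on a list, the probe set with the highest mean signal was used. Of these lists 32 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, against all other genes. The list of sex-linked genes had 2 of 5 genes measured and was not tested. Each camera call was repeated with the correlation estimated from the data, and fry was run on the same lists. Counts of rises and falls within a called list are given over all tested probe sets and adjusted over the list alone.

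Genes were named by a fixed rule. Dmd and its relative Utrn are given for every group. At each age the 8 largest rises and 5 largest falls among called probe sets were taken, provided that all 3 mdx arrays lay on the same side of all 3 control arrays, with 1 probe set per gene. For the mean, the differences between ages and the ageing of controls the 8 largest rises and 5 largest falls were taken, and for the F test the 10 lowest adjusted p. Members of lists were taken among called ones in the order of their adjusted p over the mean of the ages. A gene named outside this rule is said to be so. Where several probe sets read a gene named for the size or the F test of its change and did not behave alike, this is stated, while members of lists are given by the probe set of the list.

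The steps were tested on simulated data built from the 28-day comparison, with all 9291 probe sets and 50 probe sets changed at each of 4 sizes. At log2 changes of 0.5, 1, 2 and 3 the fit found 6%, 62%, 80% and 96% of the changed probe sets. Among its 134 calls 12 were unchanged probe sets, or 8.96%. A shifted list was found and 0 of the other lists were, but probe sets were drawn independently, unlike real lists (correlation estimated at 0.84 for liver).

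The alternatives tried were a lower or a higher pseudocount, no filter and a filter at percentile 60, quantile normalization, array weights, the replicate number as a block, a fit on the 6 arrays of a comparison alone, each array left out in turn, and for lists all probe sets of a gene. After the data had been seen, 3 more were added. These used the ratio of the 3' to the 5' Gapdh control probe set as a covariate, used albumin signal as a covariate, or left out the arrays with albumin above 10000. Python 3.11.15 was used to read the annotation and draw the plots.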

Results

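Expression in the diaphragm was profiled on 36 arrays. Control mice and mdx mice, a model of muscular dystrophy in which a point mutation of Dmd stops production of full-length dystrophin, were compared at 7, 14, 23, 28, 56 and 112 days, with 3 arrays per group. The highest signal of an array ran from 23858 to 92204. Arrays of a group correlated with r between 0.884, within the mdx group at 7 days, and 0.975, within the controls at 23 days. The leading principal component held 30.9% of the variance, the next 13% and the one after it 8.87%. On the leading component mdx replicate 1 at 7 days lay at 38.8, against -22.4 and -17.3 for the other arrays of its group. All 14-day arrays lay at 28.7 to 46.4 and all 23-day arrays at -53.9 to -38.7. Their median signals were 663 to 687.8 and 450.6 to 515.2, so this split may be technical, which was not tested. Eif2s3y, a Y-linked gene, read at least 654 on every array, and Xist, which is transcribed from the inactive X chromosome of females, read at most 223.

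Albumin (Alb), a protein made by liver cells, read above 10000 on 9 of the 36 arrays. These were control replicate 3 (25494) and mdx replicate 1 (35487) at 7 days, and control replicates 2 (33932) and 3 (30109) and mdx replicate 3 (34652) at 14 days. At the older ages they were control replicate 1 (15483) at 56 days, and control replicates 2 (18782) and 3 (37444) and mdx replicate 2 (15430) at 112 days. At 56 days the mdx arrays read 179.4 to 347.2 for albumin and the control arrays 668.1 to 15483. The ratio of the 3' to the 5' Gapdh control probe set, which can reflect the state of the RNA or its labelling, ran from 0.0357 to 0.971. What it measures on this type of array was not established here. At 7 days it was 0.147, 0.0555 and 0.0357 in controls and 0.83, 0.32 and 0.704 in mdx. At 28 days it was 0.244, 0.036 and 0.0578 in controls and 0.66, 0.105 and 0.0558 in mdx. The same ratio for actin was 0.862 to 0.944 in controls and 0.448 to 0.879 in mdx at 23 days. It was 1.01 to 1.21 and 0.35 to 1.17 at 56 days, and 0.53 to 1.68 and 0.193 to 0.937 at 112 days. At 7 and 28 days its highest value was on an mdx array.

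Dystrophin mRNA, read by 1 probe set for Dmd (93623_at), was lower in mdx than in control diaphragm as a mean over the 6 ages, by a log2 difference of -1.01 ± 0.122 (SE, adjusted p = 2.22e-07). The mdx allele is not a deletion, so its transcript can still be read, and its level tests the labels only in part. The mean signal was 718.9 ± 61.3 (SD, n = 3) in controls and 519.8 ± 167 in mdx at 7 days. It was 776.4 ± 213 and 330.2 ± 117 at 14 days and 468.7 ± 140 and 170.8 ± 32.6 at 23 days. At 28 days it was 489.9 ± 40.1 and 300.3 ± 33.7, then 673.4 ± 125 and 206.1 ± 33.1 at 56 days, and 745.4 ± 290 and 379.8 ± 146 at 112 days. Dmd was called lower at 23 days (log2 -1.28, adjusted p = 0.00954), 56 days (-1.56, adjusted p = 0.000455) and 112 days (-0.90, adjusted p = 0.0452), each with an SE of 0.299. Its log2 difference was -0.48 at 7 days (adjusted p = 0.577), -1.17 at 14 days (adjusted p = 0.13) and -0.65 at 28 days (adjusted p = 0.337), none of which was a call, although array weights gave a call at 14 days (-1.26, adjusted p = 0.0281). The 23-day call was lost without control replicate 2 (-1.08, adjusted p = 0.091) or mdx replicate 1 (-1.16, 0.0888), with the replicate block (0.0539) and on its own 6 arrays (0.0662). The 112-day call was lost without control replicate 1 (-0.64, adjusted p = 0.232) or 2 (-0.85, 0.121) or mdx replicate 1 (-0.73, 0.156) or 2 (-0.80, 0.148). It was also lost with no filter (0.0608), with the block (0.105), on its own 6 arrays (0.305) and without the arrays with albumin above 10000 (-1.31, 0.0574). Utrophin (Utrn), the autosomal relative of dystrophin, was read by 2 probe sets and was not called at any age in the fit to all arrays. For 92507_at the log2 differences from the youngest to the oldest age were -0.31, 0.07, -0.29, -0.13, 0.29 and 0.34, with an SE of 0.278 and adjusted p of 0.483 or more. For 92508_s_at they were -0.23, -0.36, -1.01, -0.11, 0.43 and 0.77, with an SE of 0.391, and the lowest adjusted p was 0.187, at 23 days. At that age 92508_s_at was called lower with array weights (-1.58, adjusted p = 0.000314) and without mdx replicate 3 (-1.60, adjusted p = 0.00698).

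**Figure D1:**
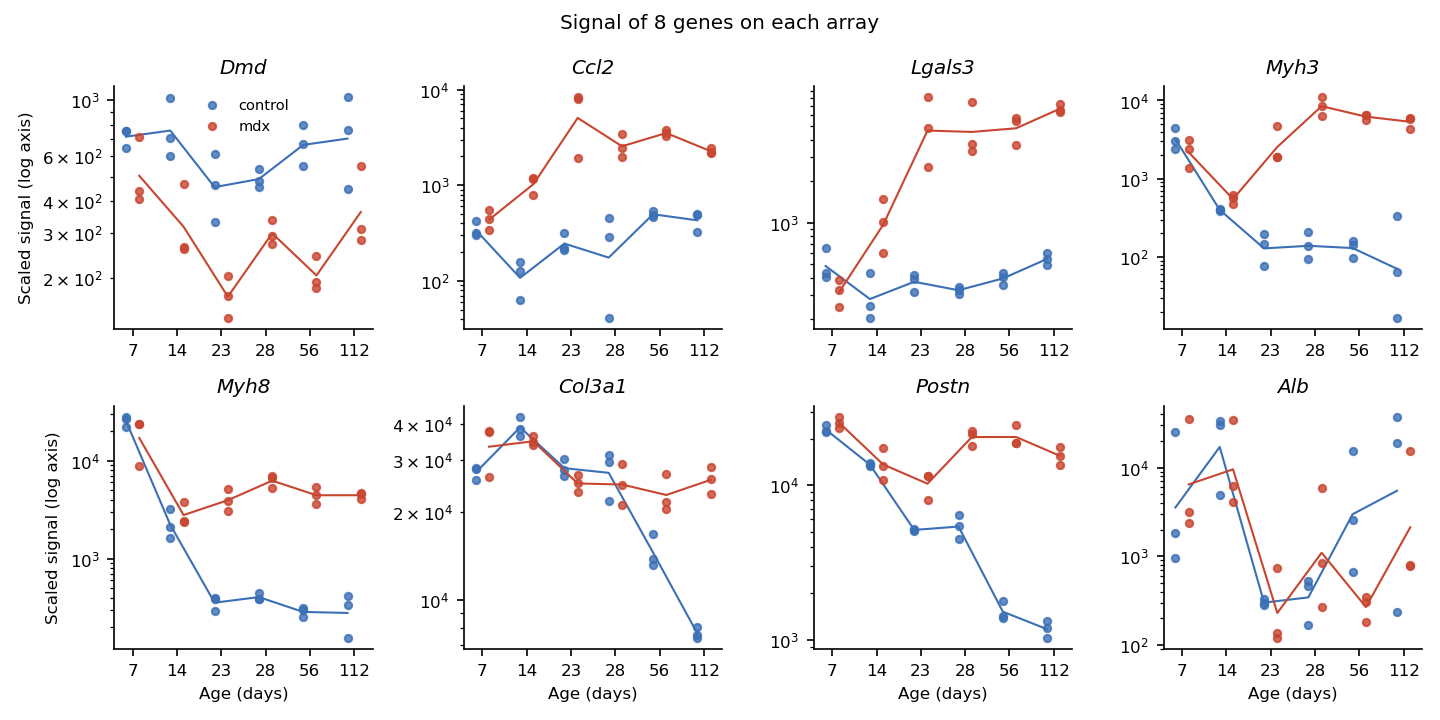
Signal of 8 genes on each of the 36 arrays (vertical log axis, deposited intensity) against age in days (horizontal axis), with a point per array, controls in blue, mdx in red, and lines through the geometric mean of each group of 3. Myh3 fell in controls from a mean of 3313 at 7 days to 138.3 at 23 days and stood at 2817 in mdx at 23 days, while albumin spread widely within groups.

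The number of genes that separated mdx from control diaphragm was low at 7 and 14 days and higher from 23 days on. At 7 days 5 probe sets were higher and 38 lower in mdx, at 14 days 15 and 3, and at 23 days 249 and 75. At 28 days the counts were 225 and 50, at 56 days 861 and 686, and at 112 days 711 and 420, of 9291 tested. The share of probe sets whose 3 mdx arrays all lay on one side of all 3 control arrays was 15.4%, 12.9%, 22.9%, 21.5%, 36.9% and 23.5% from the youngest to the oldest age, where chance gives 10%.

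**Figure D2:**
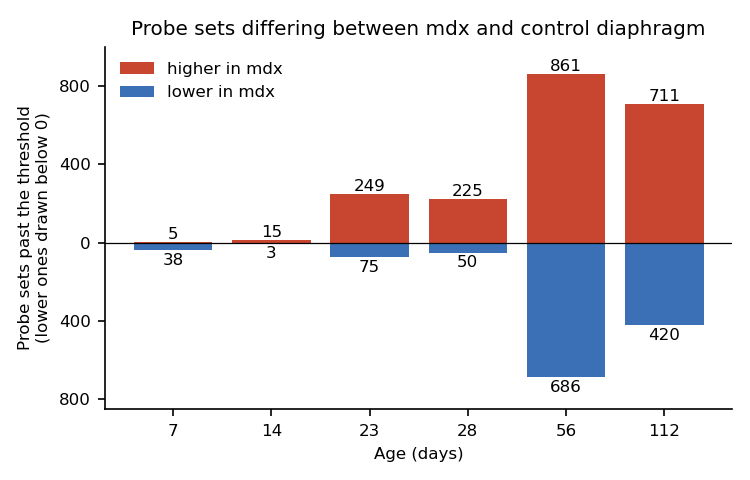
Number of probe sets past an adjusted p of 0.05 in limma (vertical axis) at each age in days (horizontal axis), with probe sets higher in mdx in red above 0 and those lower in mdx in blue below 0. The counts ran from 15 higher and 3 lower at 14 days to 861 higher and 686 lower at 56 days.

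At 7 days, before most of the later differences, mdx diaphragm differed from control mainly by lower signal of a few genes. Mmp9, a matrix metalloproteinase carried by neutrophils among other cells, fell from 1781 ± 1210 to 83.07 ± 7.98 (SD, n = 3), a log2 difference of -3.59 ± 0.504 (SE, adjusted p = 0.000188). Parvalbumin (Pvalb, 96720_f_at), the calcium buffer of fast fibres, fell by 2.85 on the log2 scale (SE 0.253, adjusted p = 2.28e-08), while its second probe set, 96719_i_at, gave 0.29 (adjusted p = 0.89). Further falls were in the hair keratin associated gene Krtap8-1 (-2.50 ± 0.582, adjusted p = 0.0396) and the homeobox gene Hoxc9 (-1.93 ± 0.357, adjusted p = 0.00508). Erdr1 also fell (98525_f_at, -2.02 ± 0.315, adjusted p = 0.000839, with -0.20 for the other probe set). The homeobox gene Hoxa5 rose by 0.87 ± 0.149 (adjusted p = 0.00257). Snrpb2, a splicing factor, rose by 0.87 (adjusted p = 0.0396, with 0.21 for the other probe set), Sprr2e by 0.69 (adjusted p = 0.03) and Tmem37 by 0.63 (adjusted p = 0.0439). The remaining riser, Meg3, an imprinted noncoding RNA, falls outside the naming rule and was named after its values were seen (160172_at, 2.45 ± 0.571, adjusted p = 0.0396, with -0.16 for the other probe set). In total 990 probe sets had an unadjusted p under 0.05 in limma.

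Listed genes that fell at 7 days were spread over several lists. They were Cacng1, a subunit of the muscle calcium channel (-1.61 ± 0.189, adjusted p = 7.58e-06), Mybph, a myosin binding protein of young muscle (-1.11), and myostatin (Mstn, -0.93), which limits muscle growth. Others were the carbonic anhydrase Car3 (-1.29) and the growth arrest gene Gadd45a (-0.92). The Schwann cell list of 9 measured genes held 2 falls, the myelin genes Mbp (-1.18, adjusted p = 0.0245, other probe set 0.60) and Pmp22 (-0.71, adjusted p = 0.0133), and was not called (camera adjusted p = 0.612). Muscle proteolysis was the list called lower: of 18 measured genes 1 fell, and 3 fell adjusted over the list alone (camera adjusted p = 0.00477, adjusted p = 0.373 with an estimated correlation). Oxidative phosphorylation was called higher with 0 of 36 genes past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0379, adjusted p = 0.869 with an estimated correlation). The Gapdh ratio differed between the groups at this age, as given above, and with it as a covariate the number of calls was 10 and the oxidative phosphorylation list was called lower (adjusted p = 0.00476). Fitting the 6 arrays of this age alone gave 0 calls in limma, with 723 probe sets at an unadjusted p under 0.05. The count of 43 was 71 with array weights, 24 with the replicate block and 13 without the arrays with albumin above 10000. Leaving out control replicate 1 gave 17 calls and leaving out mdx replicate 1 gave 23, and the calls of Krtap8-1, Snrpb2, Sprr2e and Tmem37 were lost without any of several single arrays. Sprr2e gave 0.39 without mdx replicate 1 (adjusted p = 0.403).

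At 14 days the largest rises in mdx were in a gene of antigen presentation and a chemokine. H2-Aa, a chain of the class II molecules that present antigen, rose from 278.9 ± 39.4 to 2691 ± 834 (SD, n = 3), by 3.09 ± 0.403 on the log2 scale (SE, adjusted p = 0.000132). The monocyte chemokine Ccl2 rose from 115 ± 47.5 to 1043 ± 226 (log2 2.90 ± 0.458, adjusted p = 0.00101), and the macrophage lectin Lgals3 rose by 1.68 ± 0.328 (adjusted p = 0.0161). Also higher were Tiparp, a target of the aryl hydrocarbon receptor (2.02 ± 0.31, adjusted p = 0.00101), and the interleukin 18 receptor Il18r1 (1.69, adjusted p = 0.0443). So were the DNA repair gene Xrcc1 (1.66, adjusted p = 0.0086, with 0.72 for the other probe set), the replication factor Rfc4 (1.65, adjusted p = 0.0369) and the class I gene H2-D1 (97541_f_at, 1.61, adjusted p = 0.00126, with 0.23 and 0.06 for its other probe sets). Erdr1 fell by 1.75 (98525_f_at, adjusted p = 0.0067, with -0.74 and no call for the other probe set) and Arl14ep by 0.80 (adjusted p = 0.0415, with -0.40 and no call for the other). The remaining fall, Wbp4, a splicing protein, lies outside the naming rule and was named after its values were seen (-1.54 ± 0.313, adjusted p = 0.0232).

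The class II presentation list was higher at 14 days, with 3 of 12 measured genes up and 5 adjusted over the list alone (camera adjusted p = 3.69e-07, adjusted p = 0.0258 with an estimated correlation). Its risers were the protease Ctss (1.48 ± 0.21, adjusted p = 0.000343), the invariant chain Cd74 (0.93, adjusted p = 0.0443) and H2-Aa. Another list called higher was macrophage with 2 of 25 genes up (3 adjusted over the list alone, camera adjusted p = 0.000931, adjusted p = 0.523 with an estimated correlation). Chemokine and cytokine genes had 1 of 17 up (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.0316, adjusted p = 0.138 with an estimated correlation). Oxidative stress and iron genes had 1 of 21 up, the metallothionein Mt2 (1.49), and 4 adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.138 with an estimated correlation). Immediate early and heat shock genes had 0 of 20 up over all genes and 0 over the list alone (camera adjusted p = 0.000194, adjusted p = 0.0637 with an estimated correlation). In total 609 probe sets had an unadjusted p under 0.05 in limma. The count of 18 calls became 7 to 20 with 1 array left out, 39 with array weights, 10 with the replicate block and 6 in a fit on these 6 arrays alone. Il18r1 (1.51 to 1.86), Lgals3 (1.37 to 1.65), Xrcc1 (1.44 to 1.63), Rfc4 (1.33 to 1.72), Erdr1 (-1.67 to -1.41) and Arl14ep (-0.80 to -0.61) lost their call in 2 to 5 fits without an array, at these differences. Without the arrays with albumin above 10000, which leaves 1 control array at this age, 7 of the 8 named rises lost their call. These were Ccl2 (2.93, adjusted p = 0.203), Lgals3 (2.15, adjusted p = 0.0839), Tiparp (2.11, adjusted p = 0.053), Xrcc1 (1.87, adjusted p = 0.053), Rfc4 (1.18, adjusted p = 0.525), Il18r1 (1.09, adjusted p = 0.708) and H2-D1 (0.82, adjusted p = 0.452), and the chemokine list lost its call as well (adjusted p = 0.307). A higher pseudocount also ended the calls of Il18r1 (1.12, adjusted p = 0.0644) and Rfc4 (1.08, adjusted p = 0.0927).

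At 23 days genes of immature muscle and of macrophages were higher in mdx diaphragm. The embryonic myosin light chain Myl4 (160487_at) rose by 4.32 ± 0.256 on the log2 scale (SE, adjusted p = 6.03e-13), with 0.39 and no call for its other probe set (100828_at). Embryonic myosin heavy chain Myh3 rose from 138.3 ± 59.5 to 2817 ± 1630 (SD, n = 3; log2 3.99 ± 0.445, adjusted p = 3.12e-07) and the perinatal heavy chain Myh8 by 3.36 ± 0.297 (adjusted p = 7.28e-09). Ccl2 rose from 249.1 ± 56.1 to 6096 ± 3600 (4.20 ± 0.458, adjusted p = 2.41e-07) and the related chemokine Ccl7 by 3.56 (adjusted p = 7.81e-06). Lgals3 rose by 3.53 (adjusted p = 1.44e-08), the aspartic protease Napsa by 3.12 (adjusted p = 4.92e-06) and the stretch responsive gene Ankrd1 by 3.05 (adjusted p = 7.79e-08). The largest fall was in Erdr1 (98525_f_at, -2.74 ± 0.315, adjusted p = 4.96e-07, with 0.12 and no call for the other probe set). It was followed by the histone gene H3c14 (-2.49, adjusted p = 0.0284) and Tbc1d10a (161791_r_at, -2.39, adjusted p = 0.00129, with -0.30 for the other probe set). Next came Mpdz (100728_at, -1.89, adjusted p = 0.0138, with -0.21 and -0.46 for the others) and Syt11 (-1.52, adjusted p = 0.0253).

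Of 25 macrophage genes 20 rose at 23 days, 23 adjusted over the list alone (camera adjusted p = 1.87e-38). Among them were Ctss (2.72), Lyz2 (1.79), which encodes lysozyme, and the signalling adaptor Tyrobp (2.22). Of 24 regeneration genes 13 rose, 17 adjusted over the list alone (camera adjusted p = 8.62e-22). They included cardiac troponin Tnnt2, which immature skeletal muscle also makes (2.29), beside Myl4, Myh8 and Ankrd1, and with the myogenic regulator Myog (1.54), which is named for its change between ages below. Of 17 chemokine and cytokine genes 4 rose, 8 up and 1 down adjusted over the list alone (camera adjusted p = 7.79e-07), including the receptor Ccr2 (2.48) and Ccl9 (1.64). In the complement list 4 of 10 rose, 6 adjusted over the list alone (camera adjusted p = 9.1e-06), with C1qa (1.08), C1qb (1.36, other probe set -0.24) and the receptor C3ar1 (2.26). Matrix proteases and inhibitors had 5 of 22 up, 7 adjusted over the list alone (camera adjusted p = 5.84e-05), the risers including the inhibitor Timp1 (2.20), macrophage elastase Mmp12 (2.87), the protease inhibitor Cstb (1.07) and cathepsin Ctsc (1.18). Class II presentation had 2 of 12 up, 5 adjusted over the list alone (camera adjusted p = 5.21e-05). B cell genes had 2 of 11 up, 7 adjusted over the list alone (camera adjusted p = 0.000294), the risers being Cd24a (0.62) and the immunoglobulin joining chain Jchain (1.52). These 7 lists kept their call with an estimated correlation, at adjusted p of 0.000124 for macrophage, 1.29e-05 for regeneration, 0.000563 for chemokine, 0.00516 for complement, 0.00255 for proteases, and 0.0303 for both class II and B cell.

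Lists whose call at 23 days was lost with an estimated correlation were 3 higher ones and 3 lower ones. Interferon response genes had 0 of 20 up and 2 adjusted over the list alone (camera adjusted p = 0.000294, adjusted p = 0.0832 with an estimated correlation). Cell cycle had 0 of 29 by either count (0.00228, adjusted p = 0.253 with an estimated correlation). Immediate early genes had 3 of 20 up by either count, among them Egr1 (0.84) and Egr2 (1.25) (0.00714, adjusted p = 0.144 with an estimated correlation). Oxidative phosphorylation was lower with 1 of 36 down, Ndufs4 of complex I (-0.74), and 2 adjusted over the list alone (9.4e-05, adjusted p = 0.363 with an estimated correlation). Glycolysis was lower with 1 of 21 down, the phosphorylase kinase subunit Phkg1 (-0.75), and 2 adjusted over the list alone (0.00362, adjusted p = 0.297 with an estimated correlation). Fatty acid oxidation was lower with 2 of 18 down by either count, Cpt2 (-0.53), which carries fatty acids into mitochondria, and the uncoupling protein Ucp3 (-0.92) (0.000147, adjusted p = 0.162 with an estimated correlation). In structural matrix genes 4 of 39 rose without a call of the list (camera adjusted p = 0.241). Quantile normalization ended the glycolysis call (adjusted p = 0.0755) and that of H3c14 (-2.28, adjusted p = 0.0746). Without any 1 of 4 arrays H3c14 lost its call at log2 differences of -2.48 to -2.23, and Syt11 at -1.51 to -1.35. Mpdz lost its call without control replicate 1 (-1.82) or 2 (-1.79), and without mdx replicate 1 its difference was -0.95 (adjusted p = 0.266). The count of 324 was 125 to 549 with 1 array left out, 1293 with array weights and 199 in a fit on these 6 arrays alone.

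At 28 days the largest rises in mdx were in developmental myosins. Myh3 rose from 146.4 ± 57.5 in controls to 8674 ± 2340 in mdx (SD, n = 3), by 5.62 ± 0.445 on the log2 scale (SE, adjusted p = 2.23e-10). Myl4 rose from 571.8 ± 40.6 to 19160 ± 4360 (4.97 ± 0.256, adjusted p = 1.23e-14), with 0.87 for its other probe set. Myh8 rose by 3.84 (adjusted p = 1.49e-10), Tnnt2 by 3.30 (adjusted p = 1.49e-10), and Chrng, the acetylcholine receptor subunit of fetal muscle, by 3.21 (adjusted p = 4.37e-06). Among immune genes Lgals3 rose by 3.68 (adjusted p = 2.58e-09), Ccl2 by 3.53 (adjusted p = 4.7e-06) and Chil3, a chitinase-like protein of activated macrophages, by 3.19 (adjusted p = 0.00011). The falls were Erdr1 (98525_f_at, -2.04, adjusted p = 6.86e-05, with -0.29 and no call for the other probe set), the fatty acid desaturase Scd1 (94057_g_at, -1.81, adjusted p = 0.00115, with -1.52 and 0.28 for its other probe sets), and the endothelial transcription factor Klf2 (-1.78, adjusted p = 0.0191). Also lower were the methyltransferase Inmt (-1.73, adjusted p = 0.00396) and Pvalb (96720_f_at, -1.23, adjusted p = 0.00276, with 0.30 for the other probe set).

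Regeneration genes rose in 15 of 24 cases at 28 days, 18 adjusted over the list alone (camera adjusted p = 4.41e-35), with Ankrd1 at 2.97 beside Myl4, Tnnt2 and Myh8. Macrophage genes rose in 15 of 25, 20 adjusted over the list alone (camera adjusted p = 5.85e-31), with Ctss at 2.92, Lyz2 at 1.66 and Tyrobp at 1.82 beside Lgals3. Matrix proteases and inhibitors rose in 6 of 22, 10 up and 1 down adjusted over the list alone (camera adjusted p = 9.5e-08), with Timp1 at 1.49 and Mmp12 at 2.92. Chemokine genes rose in 4 of 17, 8 up and 1 down adjusted over the list alone (camera adjusted p = 1.72e-05). Complement genes rose in 4 of 10, 5 adjusted over the list alone (camera adjusted p = 6.89e-06). With an estimated correlation the adjusted p of these 5 lists were 1.68e-07, 0.000389, 0.000191, 0.00229 and 0.00505 in the order given. Structural matrix genes rose in 5 of 39, 8 adjusted over the list alone (camera adjusted p = 0.000508, adjusted p = 0.0894 with an estimated correlation). They were led by periostin (Postn, 1.92 ± 0.163, adjusted p = 9.68e-10) and tenascin (Tnc, 2.35), both matrix proteins of injured tissue, with the collagens Col5a2 at 0.61 and Col8a1 at 1.12. Cell cycle genes rose in 2 of 29, Ccnb2 (0.84) and Birc5 (1.22), 9 adjusted over the list alone (1.9e-06, adjusted p = 0.0704 with an estimated correlation). Class II presentation had 1 of 12 up, 2 over the list alone (0.000375, adjusted p = 0.0716 with an estimated correlation). Interferon response had 0 of 20 by either count (0.00301, adjusted p = 0.139 with an estimated correlation).

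The lists lower at 28 days all lost their call with an estimated correlation. Adipocyte genes fell in 2 of 12, Car3 (-0.90) and Scd1 (94056_at, -1.52), 3 adjusted over the list alone (camera adjusted p = 0.000508, adjusted p = 0.102 with an estimated correlation). Endothelial genes fell in 1 of 13, the receptor Tie1 (-0.70), 4 adjusted over the list alone (0.000337, adjusted p = 0.0762 with an estimated correlation). Glycolysis genes fell in 1 of 21, Phkg1 (-0.76), 2 over the list alone (0.00301, adjusted p = 0.295 with an estimated correlation). Fatty acid oxidation (0.000165, adjusted p = 0.139 with an estimated correlation) and oxidative phosphorylation (0.00129, adjusted p = 0.479 with an estimated correlation) were called with 0 genes past the threshold by either count. Slow fibre genes were called with 0 of 9, and 1 adjusted over the list alone (0.0486, adjusted p = 0.479 with an estimated correlation). In total 1176 probe sets had an unadjusted p under 0.05 in limma. The slow fibre call was also lost with quantile normalization (adjusted p = 0.0631). Without control replicate 1 or mdx replicate 2 the oxidative phosphorylation (0.175 and 0.257), glycolysis (0.0678 and 0.113) and slow fibre lists (0.337 and 0.66) were not called. Nor was the slow fibre list without control replicate 3 (0.0508) or mdx replicate 3 (0.0887). The count of 275 became 148 to 239 with 1 array left out and 519 with array weights. Klf2 was not called in 4 of the 6 fits that left out an array (-1.77 to -1.35), and Inmt not without mdx replicate 3 (-1.18, adjusted p = 0.105).

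At 56 days structural matrix genes were higher in mdx and genes of energy metabolism were lower, with the tests in the next 2 paragraphs. Myl4 rose by 5.70 ± 0.256 on the log2 scale (160487_at, SE, adjusted p = 1.28e-16, with 1.78 for its other probe set) and Myh3 from 132.9 ± 33.5 to 6223 ± 458 (SD, n = 3; log2 5.26 ± 0.445, adjusted p = 5.9e-10). Chrng rose by 3.92 (adjusted p = 5.08e-08), Myh8 by 3.81 (adjusted p = 1.32e-10) and Tnnt2 by 3.52 (adjusted p = 2.77e-11). Postn rose by 3.73 ± 0.163 (adjusted p = 1.22e-16), Lgals3 by 3.51 (adjusted p = 4.84e-09) and C1qtnf3, a secreted relative of complement C1q, by 3.47 (adjusted p = 2.34e-13). The largest falls were in Mup3, a major urinary protein made by the liver (101910_f_at, -4.39 ± 1.13, adjusted p = 0.00714, with -2.79 and no call for the other probe set), and the ribosomal protein gene Rpl41 (-3.52 ± 1.06, adjusted p = 0.0202). Next came the carboxylesterase Ces1d (-3.51 ± 0.466, adjusted p = 3.04e-06), the retinol carrier Rbp4 (-3.09 ± 0.899, adjusted p = 0.0164) and keratin Krt19, present in mesothelium (-2.77 ± 0.511, adjusted p = 0.000292). Within groups, over the arrays of 7 to 28 days, the deviations of Rbp4 followed albumin with r = 0.879, those of Mup3 with 0.515, of Ces1d with 0.436, of Rpl41 with 0.334 and of Krt19 with -0.351. Those of Rpl41 followed the Gapdh ratio with 0.68. Of the 686 falls 67, or 9.77%, had r above 0.5 with that ratio in the same way, against 2.45% of all tested probe sets.

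Fatty acid oxidation genes fell in 16 of 18 cases at 56 days, 17 adjusted over the list alone (camera adjusted p = 4.24e-14, 0.00716 with an estimated correlation). They were led by the carnitine carrier Slc25a20 (-1.26 ± 0.138, adjusted p = 1.11e-07), with Cpt2 at -0.92, Ucp3 at -0.59 and Ech1 at -0.95. Glycolysis and glycogen genes fell in 14 of 21, 17 adjusted over the list alone (1.01e-11, 0.00989 with an estimated correlation). Among them were Phkg1 at -0.99, Phka1 at -0.83, the glucose transporter Slc2a4 at -0.96 (other probe set 0.53) and hexokinase Hk2 at -0.68. Oxidative phosphorylation genes fell in 17 of 36 and rose in 1, 24 and 1 adjusted over the list alone (1.82e-10, adjusted p = 0.0803 with an estimated correlation), with Ndufs4 at -0.88 and the cytochrome oxidase subunit Cox7a1 at -0.60. The single riser, Cox5a (1.72), was named after its value was seen. Slow fibre genes fell in 7 of 9 by either count (3.29e-05, adjusted p = 0.0803 with an estimated correlation). They included the slow myosin light chain Myl3 (-1.28), slow heavy chain Myh7 (-0.68) and tropomyosin Tpm3 (-0.79). Fast fibre genes fell in 2 of 13, 4 adjusted over the list alone (0.00155, adjusted p = 0.273 with an estimated correlation), Actn3 (-0.99) and Pvalb (96719_i_at, -1.74, with -2.40 for the other probe set). In the dystrophin complex list of 14 genes 4 rose and 3 fell without a call (camera adjusted p = 0.774), with caveolin Cav3 (0.69) and the laminin Lama2 (0.48) up and Sspn (-0.73) and Sgca (-0.64) down beside Dmd.

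Higher lists at 56 days again held regeneration genes, with 19 of 24 up and 20 adjusted over the list alone (camera adjusted p = 3.41e-21). Macrophage genes had 19 of 25 up and 24 over the list alone (4.24e-14). Structural matrix genes rose in 20 of 39 and fell in 1, 23 and 2 adjusted over the list alone (4.67e-09), with Tnc at 2.96, Col5a2 at 1.41 and Col6a3 at 1.45. Matrix proteases and inhibitors rose in 9 of 22 and fell in 1, 14 and 2 over the list alone (0.000356), with Timp1 at 1.91 and Mmp12 at 3.19. Chemokine and cytokine genes rose in 8 of 17 and fell in 1, 11 and 2 over the list alone (0.000784), with Ccl2 at 2.75, Ccr2 at 2.26, Ccl7 at 2.33 and the chemokine Cxcl12 at -0.98. Complement genes rose in 5 of 10, 6 over the list alone (0.000404). With an estimated correlation these 6 lists had adjusted p of 1.44e-05, 0.0135, 0.00716, 0.0092, 0.0139 and 0.0249 in that order. Class II presentation (2 of 12 up, 7 over the list alone), interferon response (6 of 20, 10 over the list alone) and cell cycle (11 of 29 up and 1 down, 16 and 1 over the list alone) were also called higher. Their camera adjusted p were 0.00266, 0.00155 and 3.11e-05, and each had adjusted p = 0.0803 with an estimated correlation. Their risers included Ifi30 (1.30), Isg15 (0.81), Ifit3 (1.56), the mitotic motor Kif11 (1.31) and the cyclin Ccnb2 (1.26).

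The adipocyte, mesothelium, endothelial, erythroid and liver lists were lower in mdx at 56 days, the first 2 also with an estimated correlation. Adipocyte genes fell in 7 of 12 by either count (camera adjusted p = 2.91e-05, 0.0381 with an estimated correlation). They included Car3 at -1.58, Scd1 at -1.86, the hormone Adipoq at -1.78 and the gluconeogenic enzyme Pck1 at -1.59. Mesothelium genes fell in 4 of 8, 5 over the list alone (0.00185, 0.0372 with an estimated correlation), with Upk3b at -0.65, Rspo1 at -1.89 and mesothelin (Msln) at -1.83. Endothelial genes fell in 4 of 13, 5 over the list alone (0.00155, adjusted p = 0.0803 with an estimated correlation), with Tie1 at -0.53 (other probe set 0.02), Vwf at -0.97 and Tek at -0.74. Erythroid genes fell in 3 of 8, 4 over the list alone (0.00876, adjusted p = 0.0803 with an estimated correlation), with Car2 at -1.15, Bpgm at -1.03 and the haem enzyme Alas2 at -1.41. Liver genes fell in 1 of 14 by either count, Rbp4 (0.00278, adjusted p = 0.473 with an estimated correlation). That list was not lower with albumin as a covariate (adjusted p = 0.561, on the higher side). Albumin is itself on the list and the other members follow it, so the covariate fit cannot test the list. Quantile normalization moved the median difference of all probe sets from 0.15 to 0.005 on the log2 scale, gave 620 higher and 701 lower calls and ended the fast fibre call (adjusted p = 0.0783). The count of 1547 was 987 to 1597 with 1 array left out. Without control replicate 1, Mup3 (-3.32), Rbp4 (-2.43), Rpl41 (-3.34) and the liver list were not called (adjusted p = 0.0751, 0.114, 0.0709 and 0.0752), and Rpl41 lost its call in 3 other such fits (-3.39 to -2.60).

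At 112 days collagens, other matrix genes and developmental muscle genes were higher in mdx diaphragm. Col3a1 (98331_at) read 7677 ± 359 in controls and 25780 ± 2730 in mdx (SD, n = 3), and Postn 1172 ± 145 and 15550 ± 2100. The largest rises were in Myl4 (160487_at, 6.15 ± 0.256 on the log2 scale, SE, adjusted p = 2.89e-17, with 1.14 for its other probe set), Myh3 (5.49 ± 0.445, adjusted p = 1.44e-10), and Ankrd1 (4.45 ± 0.311, adjusted p = 7.65e-12). They were followed by the matrix protein Npnt (4.01 ± 0.382, adjusted p = 4.74e-09), C1qtnf3 (3.87 ± 0.206, adjusted p = 1.11e-14), Myh8 (3.83, adjusted p = 5.22e-11), Postn (3.69, adjusted p = 8.24e-17) and Mmp12 (3.63, adjusted p = 7.59e-07). The largest falls were in Rpl41 (-3.35 ± 1.06, adjusted p = 0.0342), urate oxidase Uox, a liver enzyme (-3.01 ± 0.948, adjusted p = 0.033), and the small GTPase Rhou (-2.82 ± 0.426, adjusted p = 1.86e-05). Next came Ces1d (-2.43 ± 0.466, adjusted p = 0.000448) and the adipocyte gene Adig (-2.41 ± 0.302, adjusted p = 9.46e-07). The within-group deviations of Uox followed albumin with r = 0.549 over the arrays of 7 to 28 days and those of Rhou with -0.59.

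Structural matrix genes rose in 20 of 39 cases and fell in 1 at 112 days, 24 and 2 adjusted over the list alone (camera adjusted p = 6.7e-14, 0.000478 with an estimated correlation). Among them were Tnc at 2.67, Col5a2 at 2.10 ± 0.143 and Col6a3 at 1.48. Regeneration genes rose in 19 of 24, 21 over the list alone (4.5e-27, 1.79e-06 with an estimated correlation). Macrophage genes rose in 18 of 25, 21 over the list alone (8.23e-17, 0.00913 with an estimated correlation), with Ctss at 2.87, Lyz2 at 1.83 and Tyrobp at 2.89. Class II presentation genes rose in 7 of 12 by either count (1.15e-05, 0.017 with an estimated correlation), with H2-Aa at 1.82, Cd74 at 1.25 and the thiol reductase Ifi30 at 2.26. Interferon response genes rose in 9 of 20, 10 over the list alone (7.45e-06, 0.0194 with an estimated correlation), with Ifi204 at 1.18 (other probe set -0.84), Igtp at 1.12 and Isg15 at 0.87. Matrix proteases and inhibitors rose in 11 of 22 and fell in 1, 12 and 1 over the list alone (3.69e-07, 0.000418 with an estimated correlation). Chemokine genes rose in 7 of 17 and fell in 1, 10 and 1 over the list alone (0.000738, 0.0149 with an estimated correlation). Complement genes rose in 4 of 10 by either count (0.000172, 0.017 with an estimated correlation), with C1qb at 2.19 (other probe set -0.02). Cell cycle genes rose in 3 of 29 by either count, among them Kif11 (2.08) and Birc5 (1.45) (0.0108, adjusted p = 0.365 with an estimated correlation).

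Fatty acid oxidation genes fell in 13 of 18 cases at 112 days, 15 adjusted over the list alone (camera adjusted p = 1.7e-10, 0.0149 with an estimated correlation), with Slc25a20 at -1.05, Cpt2 at -0.80 and Ech1 at -0.76. Glycolysis genes fell in 7 of 21, 8 over the list alone (0.000172, adjusted p = 0.155 with an estimated correlation), with Phka1 at -1.19 and Slc2a4 at -0.86. Oxidative phosphorylation genes fell in 5 of 36 by either count, among them Ndufs4 (-0.59) and Cox7a1 (-0.62) (0.000791, adjusted p = 0.444 with an estimated correlation). Adipocyte genes fell in 4 of 12, 7 over the list alone (0.000121, adjusted p = 0.0608 with an estimated correlation), with Car3 at -1.53, Scd1 at -1.95 and resistin (Retn) at -2.06. Endothelial genes fell in 5 of 13 and rose in 1 by either count (0.00735, adjusted p = 0.185 with an estimated correlation). These included Tie1 at -0.51, Vwf at -0.71 and Tek at -0.72, while the single riser, the tight junction gene Cldn5 (0.48), was named after its value was seen. Liver genes were called lower as a list with 0 of 14 past the threshold in limma by either count (0.00428, adjusted p = 0.533 with an estimated correlation). They lay on the higher side without the arrays with albumin above 10000, but albumin is on this list, so leaving out those arrays cannot test it. Growth factor genes moved both ways without a call of their list (camera adjusted p = 0.888), with Mstn at -2.03 ± 0.194 (adjusted p = 4.74e-09), Tgfbi at 0.97, the growth factor Tgfb1 at 1.48 and the myostatin antagonist Fst at 1.93. Fitting these 6 arrays alone gave 335 calls. Without the arrays with albumin above 10000, which leaves 1 control array at this age, 605 were called. Rpl41 and Uox were called in 1 and 2 of the 6 fits that left out an array, at -3.45 to -3.07 and -3.03 to -2.45 in the others, and Uox gave -1.88 without the arrays with albumin above 10000 (adjusted p = 0.2). Without control replicate 3 the oxidative phosphorylation (adjusted p = 0.114), cell cycle (0.114), endothelial (0.0562) and liver (0.321) lists were not called. Nor were the cell cycle list without mdx replicate 3 (0.0548) and the liver list without mdx replicate 1 (0.0659).

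Over the mean of the 6 ages, the largest rises in mdx diaphragm were in Myl4 (160487_at, log2 3.68 ± 0.104, SE, adjusted p = 4.2e-22, with 0.71 for the other probe set), Myh3 (3.37 ± 0.182, adjusted p = 4.07e-15), and Ccl2 (2.67, adjusted p = 2.05e-12). Next came Lgals3 (2.56, adjusted p = 2.04e-15), Ankrd1 (2.45, adjusted p = 1.69e-15), Myh8 (2.43, adjusted p = 7.65e-16), Mmp12 (2.24, adjusted p = 7.32e-11) and Tnnt2 (2.19, adjusted p = 2.91e-16). The largest falls were in Erdr1 (-1.80 ± 0.129, adjusted p = 3.67e-12), Pvalb (96720_f_at, -1.50 ± 0.103, adjusted p = 1.38e-12), Scd1 (94057_g_at, -1.45, adjusted p = 3.27e-09), Rpl41 (-1.45 ± 0.432, adjusted p = 0.0173) and Ces1d (-1.41, adjusted p = 1.54e-06). The other probe sets gave -0.34 for Erdr1, -0.17 for Pvalb, and -1.13 and -0.04 for Scd1. In all 969 probe sets were higher and 688 lower, and 2714 had an unadjusted p under 0.05.

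Of the 32 lists 10 were higher and 7 lower over the mean, 8 and 4 of them with an estimated correlation. Macrophage genes rose in 24 of 25, 24 adjusted over the list alone (camera adjusted p = 5.98e-28), and regeneration genes in 20 of 24, 22 over the list alone (1.7e-27). Structural matrix genes rose in 19 of 39 and fell in 1, 21 and 2 over the list alone (3.26e-09). Matrix proteases and inhibitors rose in 12 of 22 and fell in 1 (1.38e-06), and chemokine genes rose in 11 of 17 and fell in 1 (6.22e-07). Complement (6 of 10, 1.38e-06), class II presentation (8 of 12, 5.87e-07) and interferon response genes (12 of 20, 5.82e-07) also rose. Cell cycle (14 of 29 up, 1.87e-05, adjusted p = 0.0708 with an estimated correlation) and immediate early genes (6 of 20 up, 0.0133, adjusted p = 0.137 with an estimated correlation) lost their call with an estimated correlation. Fatty acid oxidation genes fell in 15 of 18 (6.56e-11), glycolysis genes in 10 of 21 (1.31e-07), adipocyte genes in 7 of 12 (5.04e-05) and endothelial genes in 7 of 13 (0.000162). Oxidative phosphorylation genes fell in 13 of 36 (1.31e-07, adjusted p = 0.156 with an estimated correlation), slow fibre genes in 4 of 9 (0.00431, adjusted p = 0.238 with an estimated correlation) and fast fibre genes in 2 of 13 (0.0382, adjusted p = 0.52 with an estimated correlation). Over the list alone the counts from proteases on were 13 up and 2 down, 13 and 1, 6, 8, 14, 17, 9, 15, 14, 8, 8, 15, 6 and 2. Quantile normalization ended the last pair of calls (adjusted p = 0.0738 and 0.339). The lists without a call over the mean were dystrophin complex (camera adjusted p = 0.532), calcium handling (0.564), T cell (0.532), B cell (0.982), neutrophil (0.982), mast cell and eosinophil (0.982), TGF-beta and growth factor signalling (0.289), oxidative stress and iron (0.745), muscle proteolysis (0.48), smooth muscle and pericyte (0.283), Schwann cell (0.886), erythroid (0.145), liver (0.06), mesothelium (0.0897), and cartilage and bone (0.982).

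**Figure D3:**
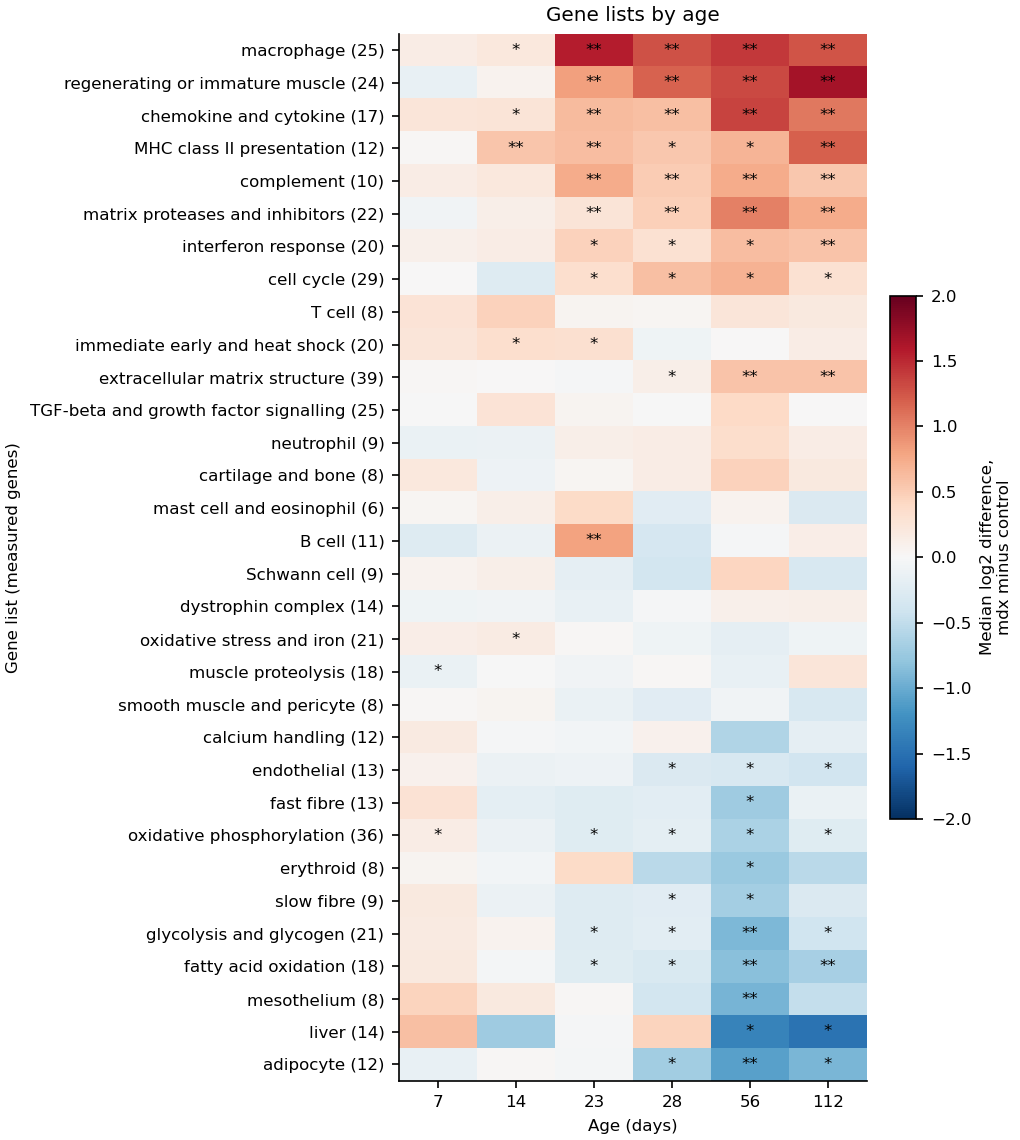
Median log2 difference, mdx minus control, of the measured genes of each of 32 gene lists (vertical axis, number of measured genes in parentheses) at each age in days (horizontal axis). A star marks a camera adjusted p under 0.05 and 2 stars one that also holds with an estimated correlation; the macrophage and regeneration lists have 2 stars from 23 days on.

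Whether the mdx effect differed between ages was tested directly. For 830 probe sets it depended on age in the F test, with 2277 at an unadjusted p under 0.05. The count was 1610 with array weights, 478 with the replicate block and 429 without the arrays with albumin above 10000. For Postn the effect ran from 0.00 at 14 days to 3.73 at 56 days (adjusted p = 2.47e-14), for Myl4 (160487_at) from -0.15 at 7 days to 6.15 at 112 days (adjusted p = 2.47e-14). For Myh8 it ran from -0.58 at 7 days to 3.84 at 28 days (adjusted p = 5.55e-10), and for Myh3 from -0.55 at 7 days to 5.62 at 28 days (adjusted p = 3.65e-09). C1qtnf3 ran from -0.16 at 14 days to 3.87 at 112 days (adjusted p = 2.2e-11). Col3a1 (102990_at) had its lowest effect at 7 days (-0.20) and its highest at 112 days (2.13, adjusted p = 1.27e-10), as did Capn6, a calpain without protease activity (-0.30 and 2.70, adjusted p = 4.98e-10, with 0.71 and 1.23 at 112 days for its other probe sets). The same ages held for the imprinted gene Peg3 (0.05 and 2.10, adjusted p = 5.98e-10, with 2.50 and 0.45 at 112 days for the others), the tubulin Tubb6 (-0.23 and 2.24, adjusted p = 6.32e-10) and Mybph (-1.11 and 2.42, adjusted p = 3.65e-09).

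Between 14 and 23 days the mdx effect rose for 24 probe sets and fell for 6, with 918 at an unadjusted p under 0.05. The genes whose effect rose included the muscle genes Myh3 (by 3.56 ± 0.63 on the log2 scale, SE, adjusted p = 0.00428), Myl4 (3.21 ± 0.361, adjusted p = 5.99e-06, with 0.33 for the other probe set), Myh8 (3.03 ± 0.42, adjusted p = 0.000226), Ankrd1 (2.42, adjusted p = 0.0056) and Myog (2.22, adjusted p = 0.0125). Others were Napsa (3.34, adjusted p = 0.00358), the antibody receptor Fcgr1 (101793_at, 2.91, adjusted p = 0.0186, with 1.51 and no call for the other probe set) and Plac8 (2.38, adjusted p = 0.000239). The effect fell for Id1, an inhibitor of differentiation (-1.43, adjusted p = 0.018), the receptor component Ramp1 (-1.26, adjusted p = 0.00271), the lipid droplet gene Plin4 (-1.16, adjusted p = 0.0437), Ucp3 (-1.09, adjusted p = 0.018) and Tcea3 (-1.05, adjusted p = 0.0476). The count of 30 was 13 with quantile normalization, which ended the calls of Myog, Plin4 and Tcea3, and 17 without the arrays with albumin above 10000. It was 9 to 139 with 1 array left out, 205 with array weights and 19 with the replicate block. Plin4 and Tcea3 lost their call in 9 of the 12 fits that left out an array, Fcgr1, Id1 and Ucp3 in 3 and Myog in 1. These but Myog, and Ramp1, were not called without the arrays with albumin above 10000, nor were Plin4, Tcea3 and Fcgr1 with the block.

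Between 28 and 112 days the mdx effect rose for 12 probe sets of 11 genes and fell for 0 in limma, with 803 at an unadjusted p under 0.05. The named genes were Col3a1 (98331_at, 1.87 ± 0.218 on the log2 scale, SE, adjusted p = 1.27e-05, with 1.59 and 0.81 for its other probe sets), Postn (1.77 ± 0.231, adjusted p = 4.29e-05), C1qtnf3 (1.71, adjusted p = 0.00243), and Col1a2 (101130_at, 1.51, adjusted p = 8.17e-05, with 0.15 for the other probe set). The others were Col5a2 (1.49, adjusted p = 7.36e-05), Trip6 (1.44, adjusted p = 0.0351), the actin binding gene Tmsb10 (1.37, adjusted p = 0.0455) and Lum (1.18, adjusted p = 8.11e-05). In controls Col3a1 read 27250 ± 1390 at 7 days and 7677 ± 359 at 112 days (SD, n = 3). The calls of Trip6 and Tmsb10 were lost with quantile normalization and in 9 and 10 of the 12 fits that left out an array (at least 1.20 and 1.23). The count of 12 was 8 to 43 with 1 array left out and 40 with array weights. Without the arrays with albumin above 10000 C1qtnf3 gave 1.39.

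Genes that rose at one age often rose at others. These comparisons share variances but no arrays, so the counts expected of independent calls may be too low. Of the 249 rises at 23 days and 225 at 28 days, 136 were shared (6.03 expected). Of the rises at 28 days 174 were also among the 711 at 112 days (17.2 expected). Of the 50 falls at 28 days 31 were among the 420 at 112 days (2.26 expected). At 56 and 112 days 351 rises (65.9 expected) and 235 falls (31 expected) were shared. Of the 15 rises at 14 days 6 were also called at 23 days (0.402 expected).

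Control diaphragm itself changed between 7 and 112 days in 3872 of 9291 probe sets, 1987 higher and 1885 lower at 112 days, with 4708 at an unadjusted p under 0.05 and 51.2% separated where chance gives 10%. The falls were led by the potassium channel subunit Kcne1l (-6.50 on the log2 scale, adjusted p = 1.48e-12) and Myh8 (-6.34, SE 0.297, adjusted p = 1.52e-16). Next came the noncoding RNA Meg3 (160173_at, 24310 ± 358 at 7 days and 743 ± 176 at 112 days, adjusted p = 1.21e-17, with a log2 difference of -1.63 for the other probe set), Capn6 (-4.99, adjusted p = 1.83e-18) and the angiotensin receptor Agtr2 (-4.88, adjusted p = 1.73e-10). The largest rises were in Mup3 (6.21 ± 1.13, adjusted p = 6.9e-05), Rpl41 (5.54 ± 1.06, adjusted p = 0.000124), and Mup5 (5.21, adjusted p = 3.25e-05). They were followed by the amylase Amy1 (4.83, adjusted p = 1.16e-11), Inmt (4.24, adjusted p = 2.44e-10), Rhou (4.11, adjusted p = 7.74e-09), the immunoglobulin gene Igkv6-23 (3.87, adjusted p = 8.2e-06) and Ces1d (3.71, adjusted p = 2.56e-07). Utrn fell by 0.99 (92507_at, adjusted p = 0.00515) and 1.31 (92508_s_at, adjusted p = 0.00819), while Dmd gave -0.02 (adjusted p = 0.96). Both Utrn calls were lost with the Gapdh ratio as a covariate (-0.82 and -1.17, adjusted p = 0.108 and 0.106). Without the arrays with albumin above 10000 the differences were -0.95 and -0.31.

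Structural matrix genes fell with age in 28 of 39 cases and rose in 1, 29 and 1 adjusted over the list alone (camera adjusted p = 1.1e-15, 0.000516 with an estimated correlation), with Postn at -4.26, Tnc at -2.68 and Col5a2 at -2.65. Regeneration genes fell in 18 of 24 and rose in 1, 19 and 1 over the list alone (3.64e-11, 0.00089 with an estimated correlation), with Myl4 at -4.37 and Myh3 at -4.76. The other calls were lost with an estimated correlation. Cell cycle genes fell in 23 of 29 and rose in 1 (4.05e-07, adjusted p = 0.0708 with an estimated correlation), with Kif11 at -2.50, and smooth muscle genes in 7 of 8 (0.00352, adjusted p = 0.0655 with an estimated correlation), with Acta2 at -1.61. Dystrophin complex genes fell in 9 of 14 and rose in 1 (0.00788, adjusted p = 0.143 with an estimated correlation), with Cav3 at -0.89 and Lama2 at -1.07, and endothelial genes fell in 6 of 13 and rose in 1 (0.0102, adjusted p = 0.209 with an estimated correlation). Oxidative phosphorylation genes rose in 14 of 36 (0.000337, adjusted p = 0.378 with an estimated correlation), with Ndufs4 at 1.19. Class II presentation genes rose in 7 of 12 and fell in 1 (0.00233, adjusted p = 0.143 with an estimated correlation), with Ctss at 0.60, Cd74 at 2.33 and H2-Aa at 3.43. Interferon response genes rose in 11 of 20 (0.00233, adjusted p = 0.143 with an estimated correlation), and adipocyte genes in 8 of 12 (0.00572, adjusted p = 0.209 with an estimated correlation), with Car3 at 0.79 and Scd1 at 3.46. Oxidative stress genes rose in 7 of 21 and fell in 1 (0.0215, adjusted p = 0.143 with an estimated correlation) and immediate early genes rose in 8 of 20 and fell in 1 (0.0397, adjusted p = 0.238 with an estimated correlation). Over the list alone endothelial falls numbered 7, class II rises 8 and immediate early rises 9, with the other counts of these 10 lists the same. The Gapdh ratio was 0.0357 to 0.147 in controls at 7 days and 0.518 to 0.93 at 112 days. With it as a covariate 2291 probe sets were called and the oxidative phosphorylation list (adjusted p = 0.528), the immediate early list (0.0892) and Rpl41 (1.76, adjusted p = 0.196) were not. Without the arrays with albumin above 10000 Mup3 gave 2.33. Quantile normalization moved the median difference of all probe sets from 0.103 to 0.031.

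Genes called in mdx were set against this ageing of controls, using the 28-day and 56-day comparisons, which share variances but no arrays with it. Of the 225 rises at 28 days 120, or 53.3%, were genes that fell with age in controls, against 20.3% of all tested probe sets (Fisher's exact test, two-sided, p = 1.14e-28). At 56 days 365 of 861 rises, or 42.4%, fell with age (Fisher's exact test, p = 7.75e-55). Of the falls at that age 296 of 686, or 43.1%, rose with age, against 21.4% of all (Fisher's exact test, p = 1.07e-40). Neither genes nor calls are independent, so these p-values are descriptive.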

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

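In this part the tests of the liver genes, of the 3' to 5' signal, of the return of older genes and of the splits behind the 4 results that join ages were chosen only after the result was seen.

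The mdx effect differed between ages by a direct test of the difference, and each such result is listed here for that reason. In the F test over the 6 ages 830 probe sets passed. The mdx effect of Postn spanned 3.73 on the log2 scale between its lowest and highest age, that of Myl4 6.30, C1qtnf3 4.03, Col3a1 2.33, Capn6 3.00, Myh8 4.42, Peg3 2.05, Tubb6 2.47, Mybph 3.53 and Myh3 6.17. From 14 to 23 days 30 probe sets passed, with a change of the effect of 3.56 for Myh3, 3.34 for Napsa, 3.21 for Myl4, 3.03 for Myh8, 2.91 for Fcgr1, 2.42 for Ankrd1, 2.38 for Plac8, 2.22 for Myog, -1.43 for Id1, -1.26 for Ramp1, -1.16 for Plin4, -1.09 for Ucp3 and -1.05 for Tcea3. From 28 to 112 days 12 passed, with 1.87 for Col3a1, 1.77 for Postn, 1.71 for C1qtnf3, 1.51 for Col1a2, 1.49 for Col5a2, 1.44 for Trip6, 1.37 for Tmsb10 and 1.18 for Lum.

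Other splits of the arrays were fitted in the same way. For the mean over the ages 1 of 100 splits within ages, the real one, gave as many calls. There were 1657 real calls and 556 in the highest other, so random splits rarely reach that count. For the F test it was also 1 of 100, with 830 and 271. Mixing the labels takes away the mdx effect shared by the ages as well as its age dependence. For the F test these splits therefore cannot decide on age dependence by itself. From 14 to 23 days 10 of 100 splits gave at least the 30 calls, with 93 in the highest other, and from 28 to 112 days 10 of 100 gave at least the 12 calls, with 197 in the highest other. In both cases the other 9 were the splits that kept the real labels at the older age and mixed them at the younger, so they carried the mdx effect of the older age. That explains how a split can reach several times the real count, and these splits leave it undecided whether chance gave the counts of 30 and 12.

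The rule for these splits was changed after its first result was seen, so that a split and its mirror within an age count once. With labels drawn freely within ages in 99 draws, 0 gave as many calls for the mean (172 at most), 2 for the F test (1013 at most), 12 from 14 to 23 days (124 at most) and 17 from 28 to 112 days (664 at most). Draws that exchange most labels at an age turn a shared effect into a difference, and these made up 2, 9 and 10 of the last 3 counts. For the F test and the 2 differences between ages these draws decide nothing either.

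For each single age the 6 arrays have 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls. The real and highest other counts were 43 and 5 at 7 days, 18 and 4 at 14 days, 324 and 64 at 23 days, 275 and 0 at 28 days, 1547 and 1 at 56 days, 1131 and 41 at 112 days, and 3872 and 34 for the ageing of controls.

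Lower liver genes in mdx at 56 and 112 days went with albumin, which the studied tissue is not known for. Over the 24 arrays of 7 to 28 days, the within-group deviations of all 13 other measured liver genes followed albumin, with a median r of 0.881 (0.749 to 0.961), against -0.0203 for all genes. Liver tissue in some of the samples is a candidate source, and the highest albumin signals, 37444 and 35487, came from a control and an mdx array. A difference between the genotypes stays open, as the mean liver score differed by -1.58 on the log2 scale with p = 0.07 in an exact permutation test (two-sided). Of the 686 falls at 56 days 2.33% had r above 0.5 with albumin against 2.4% of all probe sets, but 67, or 9.77%, had r above 0.5 with the Gapdh ratio against 2.45% of all, so differences in 3' to 5' signal stay open for part of the falls.

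Lower Rpl41 at 56 and 112 days was set against differences in 3' to 5' signal between arrays. Its within-group deviations at 7 to 28 days followed the Gapdh ratio with r = 0.68, yet with that ratio as a covariate the mean log2 difference of both ages went from -3.43 ± 0.748 to -2.99 ± 0.53 (SE), which argues against the ratio as the whole cause. The actin ratio, mostly lower in mdx at these ages, was not used as a covariate, so 3' to 5' signal stays open. Liver tissue gave r = 0.334 and is not settled by it. A difference between the genotypes may remain, and in the 9 of 12 fits without an array in which Rpl41 lost its call its difference was still -3.45 to -2.60.

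The 38 lower calls at 7 days were set against 3 explanations. Without mdx replicate 1, which stood apart, 100% kept their sign and at least 50% of their size, and 21 were still called, which argues against that array as the cause. With the Gapdh ratio as a covariate all 38 kept their sign and a median of 91.9% of their size (58.2 to 134%), which argues against the ratio as the whole cause, but only 7 stayed called as the median SE went from 0.248 to 0.322. Less mature muscle in the mdx samples may contribute, since 57.9% of these probe sets were higher in controls after 14 days than at 14 days (interval 40.8 to 73.7%), against 39.2% of all. That test leaves less mature muscle open, as the interval is wide and its probe sets are not independent.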

How the results depend on the processing

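The covariates, and the fits without the arrays with albumin above 10000, were chosen only after the result was seen. Leaving out those arrays leaves the controls at 14 and at 112 days with 1 array each, which is assumed to vary like the others. The cause was not tested for any of the changes below unless stated above.

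Array weights gave more calls, with 71 for 43 at 7 days, 39 for 18 at 14 days, 1293 for 324 at 23 days, 519 for 275 at 28 days, 1610 for 830 in the F test, 205 for 30 from 14 to 23 days and 40 for 12 from 28 to 112 days. A fit on the 6 arrays of a comparison alone gave 0 calls at 7 days (limma, 723 at an unadjusted p under 0.05), 6 at 14 days, 199 at 23 days and 335 at 112 days. Quantile normalization gave 13 calls from 14 to 23 days. The Gapdh ratio as a covariate gave 10 calls at 7 days and 2291 for the ageing of controls. Without the arrays with albumin above 10000 there were 13 calls at 7 days, 605 at 112 days, 429 in the F test, 17 from 14 to 23 days, 49 from 28 to 112 days and 2308 for the ageing of controls.

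The replicate number as a block within ages gave 24 calls at 7 days, 10 at 14 days, 478 in the F test and 19 from 14 to 23 days. The numbers do not pair the arrays, as only 1 of 18 possible pairs had r above 0.1 (-0.225 to 0.147) and 3 of 18 fitted best with their own number. The blocked counts are therefore given as a check.

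Of the called lists, those kept with an estimated correlation numbered 0 of 2 at 7 days (camera), 1 of 5 at 14 days, 7 of 13 at 23 days, 5 of 15 at 28 days, 10 of 19 at 56 days, 9 of 15 at 112 days and 2 of 12 for the ageing of controls. With fry 1 list was called at 7 days and 23 for the ageing of controls. At 7 days 0 lists were called with quantile normalization, 4 with all probe sets of a gene, 6 with the Gapdh ratio as a covariate and 1 with albumin as a covariate. The direction was reversed for oxidative phosphorylation at 7 days with the Gapdh ratio as a covariate (adjusted p = 0.00476), for the liver list at 56 days with albumin as a covariate (0.561) and for the liver list at 112 days without the arrays with albumin above 10000 (0.77).

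Leaving out an array in turn gave 17 to 59 calls at 7 days, 7 to 20 at 14 days, 125 to 549 at 23 days, 148 to 239 at 28 days, 987 to 1597 at 56 days, 893 to 1169 at 112 days, 1478 to 1762 for the mean, 650 to 1036 in the F test, 9 to 139 from 14 to 23 days, 8 to 43 from 28 to 112 days and 2989 to 3824 for the ageing of controls. Lists called ran from 1 to 6 at 7 days, 4 to 9 at 14 days, 13 to 15 at 23 days, 12 to 16 at 28 days, 18 to 20 at 56 days, 11 to 16 at 112 days, 16 to 18 for the mean and 10 to 17 for the ageing of controls.

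Counts moved most for these arrays. At 7 days there were 17 calls without control replicate 1 and 23 without mdx replicate 1, and lists numbered 6, 1 and 4 without control replicates 1, 2 and 3 and 6 and 1 without mdx replicates 1 and 3. At 14 days there were 7 without control replicate 2, 11 without mdx replicate 1 and 10 without mdx replicate 2, and lists numbered 8 without control replicate 3 and 9 without mdx replicate 3. At 23 days there were 201, 213 and 203 without control replicates 1, 2 and 3, 125 without mdx replicate 1 and 549 without mdx replicate 3. At 28 days there were 181 without control replicate 3 and 148 without mdx replicate 3, and at 56 days 1022 and 1012 without control replicates 1 and 2 and 987 without mdx replicate 1. From 14 to 23 days there were 14 without control replicate 2 at 14 days, 9 without control replicate 3, 14 without mdx replicate 1 and 139 without mdx replicate 3 at 23 days, and from 28 to 112 days 43 without control replicate 3 and 21 without mdx replicate 1 at 112 days.

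Of 152 results for named genes 31 lost their call without some array and 1, Utrn at 23 days, gained one, and of 98 for lists 17 lost theirs, with 0 reversed in limma and camera. Among named genes 24 of 105 lost their call in a fit on the 6 arrays alone, 19 of 136 with the replicate block, 8 with no filter, 6 with quantile normalization, 11 with the Gapdh ratio and 6 with albumin as a covariate, and 28 without the arrays with albumin above 10000.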

Other observations

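In this part the test of the share of 28-day rises that fall with age was chosen only after the result was seen.

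A small set of genes separated all mdx from all control arrays in the same direction at each of the 6 ages. There were 8 such probe sets, where chance gives 0.00029. Higher in mdx were the metalloproteinase Adam8 (mean log2 difference 1.77 ± 0.215, SE), the complement receptor C3ar1 (1.33 ± 0.116), Tmem37 (0.66) and 1 probe set without a single gene symbol. Lower were Erdr1 (98525_f_at, -1.80), Pvalb (96720_f_at, -1.50), Mstn (-0.94) and another probe set without a single symbol. The second probe sets of Erdr1 (-0.34) and Pvalb (-0.17) were not lower at each age. The effect depended on age in the F test for Adam8 (adjusted p = 0.0349), C3ar1 (0.00203), Mstn (0.00069), Pvalb (5.41e-05) and the lower probe set without a symbol (0.00065). It was not called for Tmem37 (0.625), Erdr1 (0.0613) and the higher one (0.653).

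Some called genes belonged to lists that camera did not call at that age. At 56 days the metallothionein Mt2, which binds metals and answers to stress, rose by 2.58 on the log2 scale while 1 of 2 probe sets of catalase (Cat) fell by 1.08 and the other gave 0.37 without a call. Both genes are on the oxidative stress list. Calcium handling genes fell in 5 of 12 cases and rose in 1 (camera adjusted p = 0.0974, fry adjusted p = 0.036, lower). Of these Cacng1 rose by 0.96 and the ryanodine receptor Ryr1, the release channel of muscle, fell by 0.63. The mitophagy gene Bnip3 fell by 0.68 and was also lower at 112 days (-0.99), where the proto-oncogene Myc was higher (1.97).

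Genes that rose in mdx at 28 days were often genes that fall with age in controls. Of the 225 rises 53.3% did so, against 20.3% of all probe sets, a pattern that a return towards a younger expression state could give. It did not rest on the genes of the fixed lists, since without them 58.5% of the rises fell with age (93 of 159, against 19.9% of all). Regenerating fibres, proliferating cells or younger matrix might each carry such genes, and these were not told apart here. Nor were age and processing in the controls.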
